A study of Zea mays with 22 samples.

How the data were processed

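Total RNA of maize was measured on 22 spotted 2-colour arrays, each of which set RNA of UV-B treated tissue against its control (or, for 2 arrays, leaf under a CA bag against leaf under a PE bag). The first value table held 14 arrays with 16928 spots and the second held 8 arrays with 17296 spots. The deposited values were log2 ratios of the 2 channels, and what the authors did before deposit, including any background correction, normalization or filter, is not given in the sources used here. The log base was settled from the values themselves. Where an array repeated values often enough to tell, 22.4% to 48.5% of its repeated values equalled the log2 of a ratio of small whole numbers plus a constant for the array, against at most 9.52% for the natural log. The tables used here hold no intensities or backgrounds, so no filter on dim spots and no intensity-dependent correction was possible.

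The direction of the deposited ratios is not stated. A rule fixed before the data were examined compared oppositely wired arrays of 1 group with oppositely wired arrays of different groups. For this rule each probe was centred on its mean over the distinct profiles of its table, so the correlations differ from those of the report, which were made without that step. In the second table the median correlation across probes was 0.083 within groups (range -0.66 to 0.665) and -0.314 between groups. In the first table it was 0.147 (range -0.157 to 0.451) and -0.04. By that rule the swapped arrays were taken as already turned. Turning every array of a table leaves the rule unchanged, so it cannot give the sign of a whole table. A positive value is read as UV-B over control, or CA over PE, by assumption. The bag titles name CA before PE, while those of the organs and regimes name UV-B only. The rule takes the reading in which arrays of a group agree more, which is also the reading with more calls. The first-table result rests on 2 pairs of arrays, and the single profiles of that table have no settled direction.

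Comparing columns of the first table showed repeated profiles, with a tolerance of 1e-06. Seedling leaf arrays 1 and 2 differed by a constant of 0.06 (with 3463 spots blank in only 1 of them), root arrays 1 and 2 by -0.21, tassel arrays 1 and 2 by 0.53 and immature ear arrays 3 and 2 by -0.29, while immature ear array 1 was identical to tassel array 1 at all 15749 spots with a value. Each distinct profile was therefore used once, which left 9 profiles of the 14 arrays. This departs from the planned design, in which all arrays of a table entered the fit, because a repeated column would otherwise count as a replicate. The seedling profile was taken from its less filled column, a choice made after the values were seen, with the fuller column as an alternative. The test of each of seedling leaf, tassel, root and ear against 0 could not be made with 1 profile each, and these are given as values.

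Every 3 consecutive spots were 1 probe and were averaged, which gave 5640 and 5760 probes. Each array was centred on its median. Deposited medians of the first table were 0.03 and 0.10 for seedling leaf, 0.0045 and -0.39 for adult leaf, 0.07 and -0.10 for CA against PE, -0.09 and -0.31 for root, 0.15 for PE-covered leaf, 0.06, -0.16 and 0.13 for immature ear, and 0.06 and 0.59 for tassel. Those of the second table lay between -0.07 and 0.05. Print position was inferred from the order of the spots as 8 blocks, and 12 positions in each of the 8 blocks were read as a source plate of 96 wells.

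Gene names came from the platform annotation, which paired 399 accessions with 329 gene symbols. They cover 401 and 406 probes of the tables, with 41 genes named by LOC number only and 2 accessions that carry several genes, which were left unnamed. Of the 329 genes, 314 were found in the reference gene table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. The 15725 and 16078 spots outside the annotation are unnamed here, and no coordinates are given.

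Each comparison was fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on the centred log2 ratios, with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Probes needed a value on every array of the groups compared and at least 1 residual degree of freedom. The joint fit of adult leaf and CA against PE therefore tested only probes with a value on all 4 of its arrays, 1962 in each comparison. A value on both arrays was held by 3285 probes for CA against PE and by 2035 for adult leaf, whose array 2 had a value at 32.7% of spots. Fold counts and correlations of a pair cover all probes with a value on both arrays. The 4 regimes of the second table were fitted together (3 residual degrees of freedom, prior 43.02), and adult leaf with CA against PE (1 residual degree of freedom, with an infinite prior, so that every probe there had the same SE of 0.233). Both fits held a probe-wise term for channel orientation. As the second array of each pair is the swapped one, this term is also a block on the replicate number. The contrasts between organs used the 9 distinct profiles without that term (2 residual degrees of freedom, prior 30.29), because the orientation of a repeated profile is not settled, and they assume that lone profiles vary like the leaf pairs. The labels do not say whether the arrays of a pair came from separate plants, so the spread behind each p may be technical. That spread is what remains after the orientation term, where fitted. It is drawn mostly from all probes pooled, since the prior outweighs the residual degrees of freedom. An SE or p is therefore not a measure of the spread of a gene's own 2 arrays.

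Gene lists were written before the data were examined, 18 in number, as symbol patterns and words of gene descriptions. The tables carry no descriptions, so the lists were assigned from the gene names found in the tables, after these had been seen. That gave 15 lists with members, and lists of aquaporins and of nitrogen assimilation were added, 2 in all. The lists of DNA repair, ubiquitin and proteasome, and pollen and anther markers had no member among the named genes. The others are flavonoid and phenylpropanoid, lignin and cell wall, photosynthesis, ribosomal protein, translation factor, heat shock and chaperone, oxidative stress, defence, chromatin, cytoskeleton, jasmonate and oxylipin, carbohydrate, and markers of endosperm, flower and root. Lists with at least 5 probes were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts "adjusted over the list alone" re-adjust p within a list. For a single profile, a list's median was ranked among 10000 random lists of the same size from all probes (and again from named probes), drawn without matching on expression because the tables hold no intensities.

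The rule for named genes was fixed before the data were examined. It takes, per replicated comparison, up to 10 probes with the largest mean log2 ratio in each direction among those past the threshold with the same sign on every array, with 1 probe per gene. Where fewer than 5 pass, it takes the 5 with the smallest p. It adds up to 4 members of each list by smallest p, and for a single profile the 5 highest and the 5 lowest. Unnamed probes are given by block and position, at most 2 higher and 2 lower.

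The code was tested on simulated data made from the spread of these arrays, with 100 probes changed at each size. The simulated noise was independent, with 1 spread for all probes and arrays of a fit and a dye effect shared by its groups. It held no block or plate offsets and no arrays that run against each other, so the rates below need not hold for the real arrays. A log2 change of 1 was recovered in 100% of probes in each of the 4 regimes (2 h high, 4 h medium, 8 h low, 8 h high), in 93% for adult leaf and in 85% for CA against PE. A change of 0.5 was recovered in 60%, 67%, 62% and 63% in the regimes, in 16% for adult leaf and in 14% for CA against PE. False calls numbered 6, 6, 9 and 3 in the regimes, 10 for adult leaf and 6 for CA against PE.

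Alternatives planned before the data were examined were no centring, scale normalization, no orientation term, the other sign reading, fits of the comparison's own arrays, complete probes, robust empirical Bayes, array weights, probes of a gene averaged, leaving out each array, and a fold of 1.5 in place of 2. Alternatives added after the data were seen were block medians and plate medians set to 0, source plates 37 and 39 left out, the choice of repeated columns, the orientation term in the organ contrasts, the first list patterns, leaving chn1 out of its list, and leaving out first-table arrays without the orientation term. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.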

Results

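Maize gene expression was compared between UV-B treated and control tissue on 22 arrays that carry both RNAs. The first set of 14 arrays covers organs after 8 h of UV-B, namely seedling leaf (2 arrays), adult leaf (2), tassel (2), immature ear (3) and root (2). It also holds adult leaves under CA and PE bags on exposed plants (2) and PE-covered leaves of exposed against control plants (1). Cellulose acetate film passes UV-B and polyester film absorbs it, and the labels give CA and PE only. The second set holds 4 regimes with 2 arrays each, named 2 h high, 4 h medium, 8 h low and 8 h high, with no intensities stated. Between 5541 and 16794 of 16928 spots had a value in the first set (32.7% to 99.2%), and between 14364 and 15853 of 17296 in the second (83.0% to 91.7%). The median SD of the 3 spots of a probe was 0.0313 to 0.0724 and 0.0391 to 0.0628 per array. The number of arrays limits the precision. In the first set several columns repeat 1 profile, so adult leaf and CA against PE are the groups with 2 distinct arrays, and seedling leaf, tassel, ear and root have 1 each. Values are log2 ratios with the array median at 0. Positive values are read as higher under UV-B (or under CA) by assumption, since the files state no direction and the sign rule cannot give that of a whole table. If the assumption is wrong for a table, rises and falls there exchange. With the swapped arrays read the other way, 0 probes passed limma in adult leaf (139 at unadjusted p under 0.05), CA against PE (7), 2 h high (8), 4 h medium (14), 8 h low (692) and 8 h high (167).

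The 8 h high regime asks what a long exposure at high intensity changes in expression. The chitinase gene chn1 rose most among named genes, by 2.95 ± 0.145 (SE, n = 2 arrays, 2.70 and 3.20), a fold of 7.72 (adjusted p = 1.26e-20, limma). Some genes of protein folding in the endoplasmic reticulum also rose, the protein disulfide isomerase PDIL1-2 by 0.79 ± 0.135 (SE, adjusted p = 6.97e-05) and the calnexin CNX by 0.71 ± 0.142 (SE, adjusted p = 0.000732). The proteinase inhibitor psei2 rose by 0.61 ± 0.136 (SE), PAL1, the entry enzyme of phenylpropanoid synthesis, by 0.58 ± 0.139 (SE), the MADS-box gene ZAG1 by 0.56 ± 0.137 (SE) and PDIL1-1 by 0.55 ± 0.144 (SE). PDIL1-1 measured 0.06 and 1.04 on the arrays, and a second probe of PDIL1-2 was at 0.16 (adjusted p = 0.832). The photosystem II gene psbs1, which acts in the dissipation of excess light, changed by -0.86 (SE 0.136, adjusted p = 1.93e-05) and the light-harvesting gene lhcb5 by -0.82 (SE 0.148, adjusted p = 0.000197). The starch synthesis genes Agp2 and du1 were at -0.56 and -0.47, por at -0.68 and pOMT1 at -0.68, all past the threshold. LOC100101527 (-0.64), LOC542721 (-0.51) and LOC542358 (-0.49) complete the 9 named probes that fell. In all, 106 probes rose and 91 fell of 5203 tested, among them 7 and 9 of 367 named probes, and 7 probes rose at least 2-fold on both arrays. The 2 arrays agreed little across probes, which are not independent replicates. Their Pearson correlation was 0.184 and their Spearman correlation -0.014, with the same sign in 46.4% of probes. With block medians set to 0 these correlations were 0.386 and 0.205. Leaving out 8 h high array 1 left 16 probes and leaving out array 2 left 6, and in each case chn1 was the 1 of the 16 named genes that kept its call. Without either 8 h low array 297 passed. The gene du1 lost its call without either 2 h high or 4 h medium array, as did LOC542358 without either 4 h medium array. Without the orientation term 45 probes passed, with chn1, PDIL1-2 and psbs1 the named genes that kept theirs. With plate medians set to 0 PAL1 was at 0.34 (SE 0.134) and du1 at -0.34 (SE 0.137), and both lost their calls. With the probes of a gene averaged PDIL1-2 (0.43, adjusted p = 0.0623), LOC100101527 (-0.41) and Agp2 (-0.39) lost theirs, and with array weights LOC542721, LOC542358 and du1.

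Gene lists at 8 h high gave 4 shifts in camera among 14 lists tested. All 8 probes of the 6 defence genes were positive (median 0.19, mean 0.57, adjusted p = 5e-12), 2 rose over all probes and 3 rose adjusted over the list alone. Without chn1 the other 7 probes had a median of 0.16 (adjusted p = 0.0188). Of 16 photosynthesis probes, 13 were negative and 2 fell, also 2 adjusted over the list alone (median -0.04, mean -0.18, adjusted p = 0.0102). Of 17 carbohydrate probes, 12 were negative and 2 fell, 3 adjusted over the list alone (median -0.16, mean -0.16, adjusted p = 0.0125). The heat shock and chaperone list had 3 risers among 8 probes, 3 adjusted over the list alone, with 4 probes positive and 4 negative (median 0.05, mean 0.22, adjusted p = 0.0145), and the risers are the disulfide isomerases PDIL1-1 and PDIL1-2 and the calnexin CNX, not heat shock proteins. With an estimated correlation the adjusted p was 1.05e-06 for defence, 0.00448 for photosynthesis, 0.00571 for carbohydrate and 0.0105 for chaperones. Photosynthesis lost its call without 8 h high array 1 (adjusted p = 0.133) or array 2 (0.0541), carbohydrate likewise (0.0671 and 0.0818), and chaperones without array 1 (0.242) or with the probes of a gene averaged (0.101). With the symbol patterns exactly as first written, 5 of the 18 lists reached 5 probes and 0 shifts passed camera, photosynthesis and carbohydrate among the lists tested.

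Other lists at 8 h high did not pass in camera. Of the oxidative stress probes 11 of 13 were positive, 0 passed over all probes and 1 rose adjusted over the list alone (adjusted p of the list 0.133). Flavonoid and phenylpropanoid genes had PAL1 as 1 riser of 2 probes and were too few to test, as were jasmonate and root marker genes, with 0 of 4 probes past the threshold each. ZAG1 was the 1 riser among the floral markers (adjusted p of the list 0.537). Adjusted p was 0.456 for ribosomal proteins, 0.725 for translation factors and for cytoskeleton, 0.749 for lignin and cell wall and for aquaporins, 0.943 for endosperm markers and for nitrogen, and 0.955 for chromatin, with 0 members past the threshold in each of these.

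**Figure D1:**
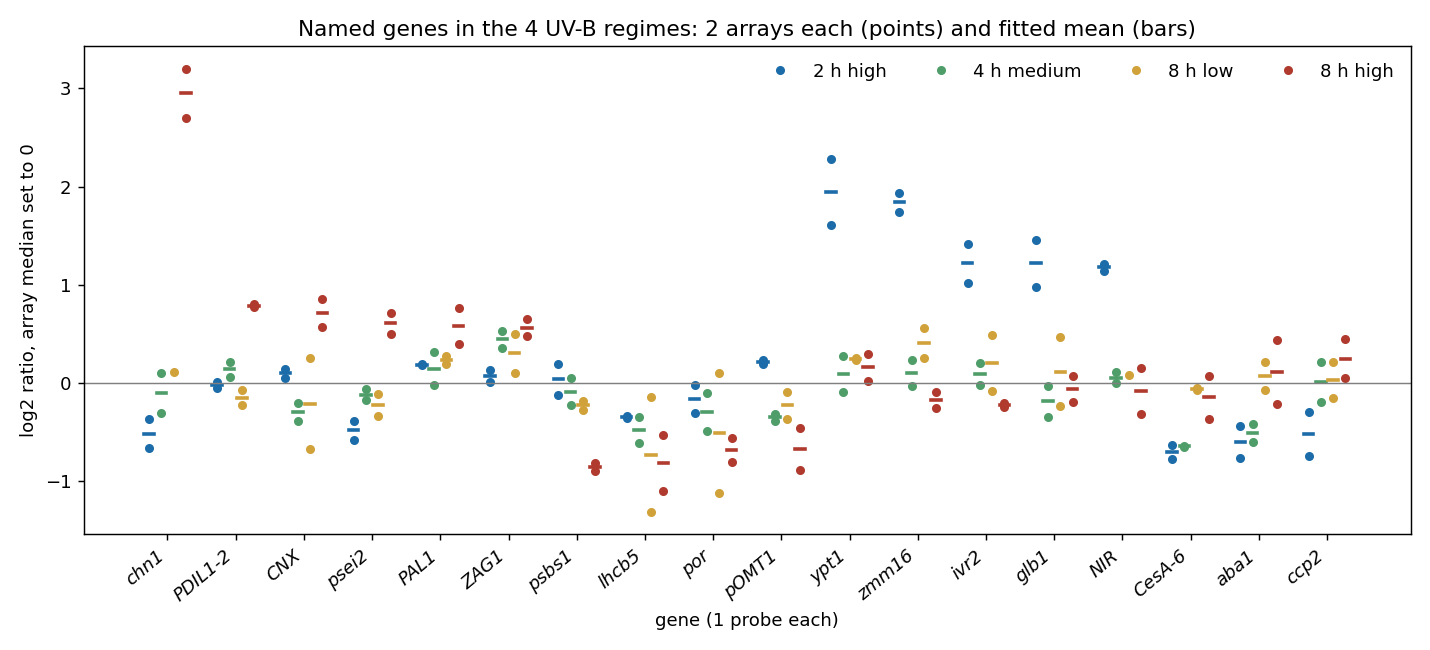
Log2 ratio (array median 0), read as UV-B over control, of 18 named genes in the 4 regimes. Each array with a value has a point and the fitted mean has a bar (chn1 and NIR at 8 h low have 1 point and no bar). At 8 h high chn1 stands at 2.70 and 3.20, and at 2 h high ypt1 stands at 2.28 and 1.61.

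The 2 h high regime asks what a short exposure changes, at an intensity that the titles also call high. The small GTPase gene ypt1 rose by 1.95 ± 0.146 (SE, n = 2 arrays, 2.28 and 1.61), a fold of 3.86, and the MADS-box gene zmm16 by 1.84 ± 0.138 (SE, both with adjusted p = 2.84e-14, limma). The invertase gene ivr2 rose by 1.22 ± 0.143 (SE), the seed storage globulin glb1 by 1.22 ± 0.136 (SE) and the aquaporin PIP1-1 by 0.81 ± 0.136 (SE). NIR (nitrite reductase) at 1.18, OBF1 at 1.05, SE1B at 0.96, ZCAX2 at 0.91 and cncr1 at 0.77 also passed. Those 5 sit on source plates 37 and 39, whose probes lay at a median of 0.86 against -0.01 elsewhere and were blank in the other regimes at 29.5% against 7.46%. Plates 57, 59 and 2 also lay above 0 on both arrays, at 0.45 and 0.27, 0.38 and 0.32, and 0.34 and 0.37. A second probe of NIR, on another plate, was at -0.09 and a second of cncr1 at 0.17. Among genes that fell, the cellulose synthase CesA-6 was at -0.71 (SE 0.136, adjusted p = 9.33e-05) and aba1 at -0.60 (SE 0.136, adjusted p = 0.00095). The cysteine protease ccp2 (-0.52), chn1 (-0.52), the expansin EXPB9 (-0.49), psei2 (-0.48), Agp2 (-0.48), GT1 (-0.50), LOC542641 (-0.53) and LOC541942 (-0.47) fell as well. In all, 573 probes rose and 141 fell of 5192 tested (13.75%), with 28 and 17 of 367 named probes, and 85 probes rose at least 2-fold on both arrays, which correlated at 0.805 across probes. Without plates 37 and 39, 587 probes passed. With plate medians set to 0, the 5 genes on these plates lost their calls as their values fell, NIR to 0.29 (SE 0.138), OBF1 to 0.27 (SE 0.133), ZCAX2 to 0.13 (SE 0.134), SE1B to 0.076 (SE 0.134) and cncr1 to -0.12 (SE 0.134). LOC542641 (-0.39), GT1 (-0.39), EXPB9 (-0.37), psei2 (-0.39) and LOC541942 (-0.31) also lost theirs. At smaller values glb1 (0.86, SE 0.135), PIP1-1 (0.58, SE 0.134) and ypt1 (1.79, SE 0.142) kept their calls. At larger ones zmm16 (1.96, SE 0.137) and ivr2 (1.29, SE 0.139) kept theirs. The share of calls that were higher, 80.3%, was 59.0% with block medians set to 0 (840 higher and 584 lower) and 50.8% with array weights (1369 and 1325). With the probes of a gene averaged CesA-6 (-0.36, adjusted p = 0.0707), EXPB9 (-0.22) and Agp2 (-0.23) lost their calls, and ivr2 (0.77), glb1 (0.70), NIR (0.54), PIP1-1 (0.50) and cncr1 (0.47) passed at smaller values. The gene chn1 lost its call with block medians set to 0 (adjusted p = 0.0599). Leaving out 2 h high array 1 left 291 probes and array 2 left 247, leaving out either 8 h low array gave 1146, and the fit without the orientation term gave 375. Without array 1, PIP1-1, aba1, LOC542641, ccp2, chn1, GT1, EXPB9, psei2 and Agp2 lost their calls, and without array 2 the same genes except PIP1-1 did, with cncr1, CesA-6 and LOC541942.

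Gene lists at 2 h high gave 0 shifts past the threshold in camera, over 14 lists tested. All 8 defence probes were negative, 3 fell (chn1, psei2 and psei3, the last by -0.40) and 4 fell adjusted over the list alone (unadjusted p = 0.0086, adjusted p = 0.12, and 0.731 with an estimated correlation). Lignin and cell wall genes had 2 risers (cncr1 and xth1, at 0.44) and 3 probes that fell among 15, and carbohydrate genes had 1 riser (ivr2) and 2 that fell (sus2 at -0.47 and Agp2) among 17, the same numbers adjusted over the list alone. The carbohydrate list had a median of 0.01 and a mean of 0.05 while the test pointed down (adjusted p = 0.959). Endosperm markers had 2 risers among 6 (glb1, and glb2 at 0.43), nitrogen genes 2 among 9 (NIR, and asn1 at 0.51), chaperones 1 among 8 (hsp70-4 at 0.49), chromatin genes 1 among 21 (sgb102 at 0.50), floral markers 1 among 8 (zmm16) and aquaporins 1 among 13 (PIP1-1). In the photosynthesis list 0 of 16 probes passed, and over all probes 0 passed among ribosomal proteins, translation factors, oxidative stress, cytoskeleton, jasmonate, flavonoid and root marker genes.

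The 4 h medium regime gave few calls in the main fit. CesA-6 was at -0.65 (SE 0.136, n = 2 arrays, -0.64 and -0.65, adjusted p = 0.00892, limma) and Agp2 at -0.57 (SE 0.137, -0.36 and -0.78, adjusted p = 0.0452), the 2 named genes that passed. By smallest p follow aba1 at -0.51 (adjusted p = 0.115), lhcb5 at -0.48 (0.296) and ZAG1 at 0.44 (0.296), which did not pass. In all 8 probes rose and 8 fell of 5280 (263 at unadjusted p under 0.05). The arrays correlated at 0.231 across probes. With scale normalization 221 probes passed (79 higher and 142 lower), with array weights 778, and without either of its own arrays or either 8 h high array 5. Both named genes lost their calls without the orientation term, with the probes of a gene averaged, and without either 4 h medium or 8 h high array, and Agp2 also without either 2 h high or 8 h low array. No list shift passed in camera (smallest adjusted p 0.103, chromatin, 21 probes), and adjusted over the list alone 1 probe each of photosynthesis, carbohydrate and lignin genes fell and 1 floral probe rose.

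The 8 h low regime rests on 2 arrays that ran against each other, with a correlation of -0.363 across 4905 probes, which are not independent replicates. The SD between probes was 0.18 on array 1 and 0.43 on array 2, so array 2 weighs more in the fitted means. The light-harvesting gene lhcb5 was at -0.73 (SE 0.148, n = 2 arrays, -0.15 and -1.31, adjusted p = 0.00738, limma) and the MADS-box gene m28 at -0.61 (SE 0.15, 0.05 and -1.27, adjusted p = 0.0489). The next named genes, MMT1 at -0.58 (adjusted p = 0.0715), Zea m 3 at -0.53 (0.0719) and hir1 at -0.52 (0.0796), did not pass, and chn1 had a value on 1 array. In all 10 probes rose and 9 fell of 4900 (753 at unadjusted p under 0.05), with 0 list shifts in camera (smallest adjusted p 0.425). Adjusted over the list alone, 1 probe each of photosynthesis, translation and defence genes fell, 2 of the aquaporins fell, and 1 floral probe rose and 1 fell. Without 8 h low array 1 the count was 1005 and without array 2 it was 3, without either 8 h high array 5, and both named genes lost their calls without array 2 or either 8 h high array. They also lost them without the orientation term, with array weights, with block medians set to 0 (lhcb5 at -0.56 and m28 at -0.48) and with scale normalization (-0.43 and -0.28), and m28 also with complete probes, with the probes of a gene averaged and without plates 37 and 39.

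Whether the response follows the product of intensity and duration was asked with 3 regimes, 2 h high, 4 h medium and 8 h low. The doses are not stated, and the word reciprocity in the titles is read as equal products of intensity and time. Among named genes ypt1 and zmm16 differed most, by 1.85 (SE 0.207) and 1.74 (SE 0.195) between 2 h high and 4 h medium and by 1.70 and 1.43 between 2 h high and 8 h low. Of the unnamed probes 5_31 (2.06) and 8_626 (1.94) differed more in the first contrast, and 8_626 (1.66) and 8_272 (1.63) more than zmm16 in the second. The globulin gene glb1 (1.41 and 1.10) and the invertase gene ivr2 (1.13 and 1.01) were also higher at 2 h in both contrasts, while CesA-6 was lower at 2 h high than at 8 h low by -0.65 (adjusted p = 0.0359) and aba1 by -0.67 (adjusted p = 0.0256). The limma F test found 291 of 4750 probes that differed among the 3 regimes, 13 of 341 named. Between 2 h high and 4 h medium 339 probes were higher and 9 lower of 5152 (845 and 536 in a fit of the arrays compared, 980 and 693 with array weights), and between 2 h high and 8 h low 238 and 13 of 4765. Between 4 h medium and 8 h low limma found 0 of 4861 (216 at unadjusted p under 0.05, smallest adjusted p 0.176), with CesA-6 at -0.59, aba1 at -0.58 and m28 at 0.64 the named genes of smallest p. Without 8 h low array 1 the F test gave 702 probes, the 2 h high to 8 h low contrast 743 and the 4 h medium to 8 h low contrast 129. Without 2 h high arrays 1 and 2 in turn the F test gave 169 and 139, the 2 h high to 4 h medium contrast 192 and 180, and the 2 h high to 8 h low contrast 151 and 109. Without 8 h high arrays 1 and 2 the F test gave 164 and 165 and the 2 h high to 8 h low contrast 130 each, and without 4 h medium arrays 1 and 2 the 2 h high to 4 h medium contrast gave 195 and 170. Without plates 37 and 39 it gave 254 and the 2 h high to 8 h low contrast 182. At 2 h high against 8 h low CesA-6 lost its call without any 1 of the 8 arrays, aba1 without any but 8 h low array 1, and ivr2 lost its call in both contrasts without 2 h high array 1. With plate medians set to 0 CesA-6 (-0.59, SE 0.189) and aba1 (-0.51, SE 0.187) lost theirs against 8 h low, as they did with array weights and in a fit of the arrays compared. With the probes of a gene averaged CesA-6 (-0.22) and glb1 (0.60, adjusted p = 0.0562) lost theirs in that contrast, and without the orientation term CesA-6, aba1, glb1 and ivr2 did.

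Duration was compared as 8 h high minus 2 h high, with both high intensities taken as equal, which the labels do not state. The gene chn1 differed by 3.47 (SE 0.205, 4 arrays, adjusted p = 1.95e-17, limma), at -0.52 after 2 h and 2.95 after 8 h, and psei2 by 1.09 (SE 0.192, adjusted p = 3.62e-05). The genes zmm16 (-2.02, adjusted p = 3.63e-10), ypt1 (-1.79, adjusted p = 1.31e-08) and ivr2 (-1.44, adjusted p = 7.3e-07) were lower at 8 h, as was psbs1 (-0.89, adjusted p = 0.000632). The folding genes PDIL1-2 (0.81) and PDIL1-1 (0.72) were higher at 8 h, as were Sod4A (0.74), ccp2 (0.77) and hir1 (0.73). The defence list was higher at 8 h in all 8 probes (median 0.46, mean 0.84, camera adjusted p = 5.76e-08, 0.000193 with an estimated correlation and 0.0172 without chn1), with 4 probes past the threshold and 4 adjusted over the list alone. In all 151 probes were higher and 428 lower of 5054. The count was 238 and 198 without 8 h high arrays 1 and 2, 300 and 260 without 2 h high arrays 1 and 2, 947 without either 8 h low array, and 467 without plates 37 and 39. PDIL1-2, ccp2 and Sod4A lost their calls without any 1 of the 4 arrays compared, hir1 without either 2 h high array or 8 h high array 2, and PDIL1-1 and psbs1 without array 2 of either regime. With plate medians set to 0 hir1 (0.54, SE 0.193) and PDIL1-1 (0.51, SE 0.196) lost theirs, with the probes of a gene averaged PDIL1-2 (0.41) and hir1 (0.47), and without the orientation term ccp2, Sod4A, hir1 and PDIL1-1.

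Intensity at 8 h was compared as 8 h high minus 8 h low. The folding genes PDIL1-2 (0.94, SE 0.19, adjusted p = 0.00618) and CNX (0.93, adjusted p = 0.0113), MMT1 (1.07, adjusted p = 0.00618) and psei2 (0.84, adjusted p = 0.0224) were higher at high intensity, while psbs1 at -0.63 did not pass (adjusted p = 0.133). The defence list (6 of 7 probes positive, median 0.35, mean 0.39, 1 past the threshold and 3 adjusted over the list alone, adjusted p = 0.0047) and the chaperone list (5 of 8 positive, median 0.27, mean 0.29, 2 past the threshold and 2 adjusted over the list alone, adjusted p = 0.0362) shifted upward, each with an adjusted p of 0.0436 with an estimated correlation. In all 21 probes were higher and 10 lower of 4866. Leaving out 8 h high array 1 or array 2 gave 0 probes in limma (575 and 195 at unadjusted p under 0.05), leaving out 8 h low array 1 gave 660 and array 2 gave 1, and all 4 genes lost their calls without either 8 h high array, without 8 h low array 2, with array weights and without the orientation term. PDIL1-2 also lost its call with the probes of a gene averaged (0.62), MMT1 (0.94) and psei2 (0.65) with block medians set to 0, and psei2 in a fit of the arrays compared. The defence list lost its call without 8 h high array 2 (adjusted p = 0.0672), and the chaperone list without 8 h high array 1 (0.261), without 8 h low array 1 (0.203) or with the probes of a gene averaged (0.223).

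Calls shared between regimes were counted among probes tested in both. The probes higher in all 4 regimes numbered 4, unnamed and printed in block 1, at positions 4 and 10 of plates 1 and 58. Probe 1_4 was at 1.43, 1.87, 2.18 and 2.39 in 2 h high, 4 h medium, 8 h low and 8 h high, and probe 1_688 at 1.05, 1.72, 1.88 and 2.07. Between 2 h high and 8 h high, 10 probes rose in both where independent lists would share 11.23, and 2 fell in both against 2.43. The other pairs shared more than independent lists would, except that 4 h medium and 8 h low shared 0 of the probes that fell (0.01 expected). Of the 8 probes higher at 4 h medium, 6 were higher at 2 h high (0.88 expected), 7 at 8 h high (0.16) and 4 at 8 h low (0.02). Of the 10 higher at 8 h low, 7 were higher at 2 h high (1.02) and 6 at 8 h high (0.2). Among probes that fell, 4 h medium shared 4 with 2 h high (0.22) and 3 with 8 h high (0.11). The 8 h low regime shared 1 with 2 h high (0.23) and 3 with 8 h high (0.16). The 4 probes of block 1 are part of each of these pairs of higher probes. In opposite directions, 8 probes fell at 2 h high and rose at 8 h high, chn1 and psei2 among them, and 7 did the reverse. The numbers that independent lists would share were not computed for opposite directions, so these counts are not read as more or fewer. Across probes, which are not independent replicates, the means of 2 h high correlated at 0.188 with 4 h medium, 0.341 with 8 h low and -0.078 with 8 h high, those of 4 h medium at 0.424 with 8 h low and 0.282 with 8 h high, and those of 8 h low at 0.191 with 8 h high.

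The adult leaf comparison asks what 8 h of UV-B changes in exposed adult leaves. Of 153 named probes, 0 passed limma. The folding gene PDIL1-2 had the smallest p, at 0.61 (SE 0.233, n = 2 arrays, 0.52 and 0.71, adjusted p = 0.286, limma), followed by LOC541942 at -0.59, the profilin PRO5 at -0.54, met2 at 0.51 and the sulfite reductase sir at -0.51. The unnamed probe 4_71 rose by 1.78 and 6_134 fell by 0.95. Of the 2035 probes with a value on both arrays, 0 were at 2-fold on both, and the arrays correlated at -0.181 across them. In all 30 probes rose and 1 fell of 1962 tested, which also needed a value on both CA against PE arrays. Without adult leaf array 1 the count was 510, without array 2 it was 16, without either CA against PE array 15, and with plate medians set to 0 it was 0 (limma, 141 at unadjusted p under 0.05, with prior degrees of freedom of 4.943 in place of infinite). Of the lists, 4 were large enough for camera and did not pass, with adjusted p of 0.586 for chromatin and for carbohydrate and 0.399 for lignin and cell wall and for aquaporins.

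Leaves under CA and PE bags on exposed plants ask what direct UV-B changes in a leaf beyond what reaches a shielded leaf. The disulfide isomerase PDIL1-2 was higher under CA by 0.90 (SE 0.233, n = 2 arrays, 0.90 and 0.90, adjusted p = 0.0054, limma), with a second probe at 0.08, and sir by 0.83 (adjusted p = 0.0156). The glycine-rich protein gene grp1 (-0.83, adjusted p = 0.0156), the sucrose phosphate synthase gene sps1 (-0.81, adjusted p = 0.0205) and the thiamine synthesis gene thi1-2 (-0.77, adjusted p = 0.0288) were lower under CA, and the rubisco activase gene rca1, at -0.69, did not pass (adjusted p = 0.0764). In all 30 probes were higher and 41 lower of 1962 tested, which also needed a value on both adult leaf arrays. Of the 3285 probes with a value on both CA against PE arrays, 19 were at least 2-fold higher and 8 lower on both. The 2 arrays correlated at 0.575 across these probes. Among unnamed probes 4_289 was at 2.11 and 4_53 at -2.54. The same 4 lists had an adjusted p of 0.86 each. With plate medians set to 0 the count was 12, without CA against PE array 1 it was 7 and without array 2 it was 4, without either adult leaf array 313, with scale normalization 123 and without the orientation term 135. All 5 named genes lost their calls without either CA against PE array and with plate medians set to 0, where their values stayed near those above, at 1.02 for PDIL1-2 (SE 0.149, adjusted p = 0.0553), 0.82 for sir (SE 0.15), -0.75 for grp1 (SE 0.185), -0.80 for sps1 (SE 0.227) and -0.71 for thi1-2 (SE 0.172). Those calls ended because limma's prior degrees of freedom went from infinite, with 1 SE of 0.233 for every probe, to 4.943, so the loss does not point to an effect of plates on these genes. With the probes of a gene averaged thi1-2 was at -0.33 (adjusted p = 0.97), and with block medians set to 0 sps1 (-0.70, adjusted p = 0.0508) and thi1-2 (-0.67, adjusted p = 0.0705) lost their calls.

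Exposed organs (seedling leaf, adult leaf, tassel) were set against shielded organs (ear, root), and adult against seedling leaf. Named genes of smallest p for exposed minus shielded were PDK2 at -0.77 (SE 0.239, adjusted p = 0.194, limma), GT1 at -0.68 and dbf1 at -0.65, none past the threshold. For adult minus seedling leaf they were thi1-2 at -1.30 (SE 0.328, adjusted p = 0.0991), ATP2 at -1.26, TOR at 1.12 and tip1 at 1.10, also not past it. The unnamed probe 4_205 was higher in exposed organs by 1.28 (adjusted p = 0.012), 1 of 1845 tested (282 at unadjusted p under 0.05), and probe 3_694 lower in adult leaf by -2.04 (adjusted p = 0.0143), 1 of 2027 (332 at unadjusted p under 0.05). Among the 5 organs the limma F test found 0 of 1843 (334 at unadjusted p under 0.05, smallest adjusted p 0.0565). Without adult leaf array 1 these counts were 384, 553 and 894, without array 2 they were 124, 56 and 277, without either CA against PE array 2, 0 and 4, and with the orientation term 6, 42 and 42. Adult leaf array 2 and the ear profile correlated at -0.516 across probes. The profiles of seedling leaf, tassel, ear and root were each deposited for both orientations, so their directions are not settled. Turning 1 of these profiles would change the size of a contrast that holds it, and so which probes pass. The calls of probes 4_205 and 3_694 and the counts above therefore hold only for the signs as deposited.

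The PE-covered leaf asks whether a shielded leaf of an exposed plant differs from a shielded leaf of a control plant. It has 1 array, no replicate check and no p, and its sign is as deposited, so turning it exchanges higher and lower. Highest were PP1 at 1.73, chn1 at 1.46, pip1-2 at 1.31, opr6 at 1.14 and MRP2 at 1.05. Lowest were lhcb5 at -1.11, the rubisco small subunit gene ssu1 at -0.96, PIP1-1 at -0.93, cda1 at -0.91 and ccp1 at -0.87. The 15 photosynthesis probes had a median of -0.31, at percentile 0.15 of random lists from all probes (10 negative), and 8 defence probes a median of 0.33, at percentile 98.94. Cytoskeleton probes (median -0.43, percentile 1.34) and floral markers (median -0.31, percentile 2.83) also lay low. Of 5189 probes, 55 were at least 2-fold higher and 52 lower.

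Single profiles of the other organs are also as deposited, with no p. In root, ZCAX2 (1.58), In2-1 (1.09), crp1 (0.87), zmm16 (0.84) and m28 (0.82) were highest, and pip1-2 (-1.24), HRGP (-0.82), PG14 (-0.78), mbd111 (-0.77) and LOC542101 (-0.72) lowest. In seedling leaf, thi1-2 (1.27), ATP2 (1.02), rop1 (0.95), glb2 (0.92) and sam2 (0.91) were highest, and gln4 (-1.24), cncr1 (-1.19), L-FNRI (-1.12), PG14 (-0.93) and MRP2 (-0.89) lowest. The tassel profile, also deposited for ear array 1, had sus1 (1.36), GRF10 (1.16), met2 (1.15), mtl2 (1.14) and gtc102 (0.90) highest and prp2 (-0.72), glb2 (-0.63), tip1 (-0.63), mbd111 (-0.63) and LOC542285 (-0.60) lowest. The ear profile had HRGP (1.12), PDK2 (0.97), du1 (0.88), GT1 (0.79) and xyl1 (0.76) highest and LOC732771 (-1.36), mbd111 (-1.05), PDIL1-2 (-0.89), TIP2-1 (-0.86) and met2 (-0.80) lowest. Probes at least 2-fold higher and lower numbered 48 and 3 of 4806 in root, 48 and 22 of 4627 in seedling leaf, 67 and 2 of 5329 in tassel, and 8 and 21 of 2935 in ear.

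**Figure D2:**
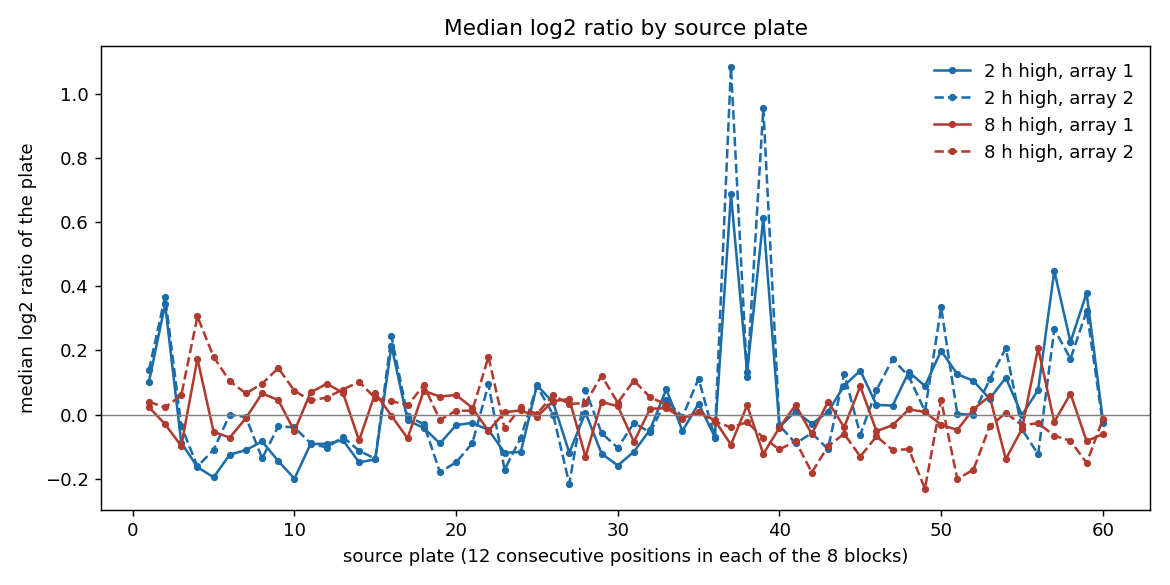
Median log2 ratio (array median 0) of the probes of each source plate, by plate number, for both 2 h high arrays and both 8 h high arrays, with a line per array. Plate 37 stands at 0.69 and 1.08 and plate 39 at 0.61 and 0.96 on the 2 h high arrays, while on the 8 h high arrays they lie at -0.09, -0.04, -0.12 and -0.07. The 4 h medium and 8 h low arrays are not drawn, and on 8 h low array 2 plates 37 and 39 lay at 0.37 each.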

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

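Of the tests below, those of the third plate explanation, of slide position and dye for adult leaf, and of dye for 8 h low were chosen only after the result was seen. The results singled out here are differences between groups that were tested as contrasts in limma or as list shifts in camera.

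Many calls at 2 h high gather on source plates 37 and 39, where 98 of 130 probes rose (75.4%) against 9.4% elsewhere. The difference of these plates from the others was 0.87 at 2 h high, 0.23 at 8 h low, 0.08 at 4 h medium and -0.09 at 8 h high. On 8 h low array 2 their medians were 0.37 and 0.37, and on array 1 they were 0.07 and 0.06. Evidence against a UV-B response of the genes concerned rests on few genes. The other probes of the 4 genes that also have a probe on another plate had a median of -0.17 at 2 h high. Of these genes NIR (1.18) and cncr1 (0.77) were clearly raised on the plates, and their other probes were at -0.09 and 0.17. PIP1-3 (0.29) and psei1 (-0.06) were raised little or not there, so they hardly test a response. The test on other probes replaced an earlier one, the plates' difference at 8 h high of -0.09. That earlier test had met its bound against a response but was dropped because a short-lived response need not persist. An offset shared by whole plates remains open and may account for these calls, as the on-plate probes of the 4 genes exceeded the other probes by a median of 0.61, with NIR at 1.18 against -0.09 and psei1 at -0.06 against -0.25. Poor measurement of these spots may contribute too, as they were blank in the other regimes 3.96 times as often as spots elsewhere, and a response of the genes with no probe elsewhere was not tested.

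The arrays of adult leaf ran against each other across probes, at -0.181. Offsets of whole plates alone, or of whole blocks alone, are argued against as the whole cause. The correlation stayed below 0 with plate medians set to 0 (-0.12) and with block medians set to 0 (-0.25). Both offsets at once, or a trend within a block that differs between blocks, were not tested. A turned sign on 1 array cannot be told apart from other causes, because array 2 correlated with CA against PE at 0.043 and array 1 at 0.189, and the first value lies within the range where the test does not decide. A dye effect of each probe is likewise open, with a correlation of 0.113 between the half-differences of the leaf pairs, and no biological explanation was tested.

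The arrays of 8 h low also ran against each other, at -0.363. Offsets of whole plates alone, or of whole blocks alone, are argued against as the whole cause. The correlation stayed negative with plate medians (-0.36) and with block medians (-0.19) set to 0. Both offsets at once, or a trend within a block that differs between blocks, were not tested. The correlation weakened with block medians, and array 2 had a range of block medians of 0.83. A contribution of block position therefore remains open. A dye effect of each probe may account for the opposition. The effect estimated from the other 3 regimes correlated at 0.596 with the half-difference of the 8 h low arrays across 4722 probes. That correlation could have been near 0. It cannot tell a dye effect from a difference tied to replicate number, which the same term holds. Nor can it tell one from the other sign reading, under which such half-differences are the values. The SD between probes was 0.18 on array 1 and 0.43 on array 2, so array 2 weighs more in that half-difference. Whether the plants of the arrays differed was not tested, nor was a turned sign on 1 array.

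For 8 h high minus 2 h high, limma found 579 probes that differed. Higher at 8 h were chn1 (3.47), psei2 (1.09), LOC541942 (0.82), PDIL1-2 (0.81), ccp2 (0.77), Sod4A (0.74), hir1 (0.73), PDIL1-1 (0.72), aba1 (0.72) and LOC541901 (0.69). Lower at 8 h were zmm16 (-2.02), ypt1 (-1.79), ivr2 (-1.44), OBF1 (-1.30), glb1 (-1.28), NIR (-1.26), PIP1-1 (-1.14), psbs1 (-0.89), pOMT1 (-0.89) and LOC100101527 (-0.85). The defence list was higher at 8 h in all 8 probes (adjusted p = 5.76e-08). OBF1 and NIR sit on plates 39 and 37.

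For 8 h high minus 8 h low, 31 probes differed, and PDIL1-2 (0.94), MMT1 (1.07), CNX (0.93) and psei2 (0.84) were higher at high intensity. The chaperone list (adjusted p = 0.0362, median 0.27 over 8 probes) and the defence list (adjusted p = 0.0047, median 0.35 over 7 probes) were higher there as well.

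Among the 3 regimes 2 h high, 4 h medium and 8 h low, the F test found 291 probes. Between 2 h high and 4 h medium 348 differed, with ypt1 (1.85), zmm16 (1.74), glb1 (1.41), ivr2 (1.13), NIR (1.13), OBF1 (0.85), LOC541857 (0.83), SE1B (0.81), glu1 (0.79) and ZCAX2 (0.75) higher at 2 h. Between 2 h high and 8 h low 251 differed, with ypt1 (1.70), zmm16 (1.43), glb1 (1.10), ivr2 (1.01), MMT1 (0.87), LOC100125656 (0.82), EF1A (0.75) and xth1 (0.63) higher at 2 h, and aba1 (-0.67), LOC541942 (-0.66) and CesA-6 (-0.65) lower. NIR, OBF1, SE1B and ZCAX2 sit on plates 37 and 39.

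Among organs, 1 unnamed probe differed between exposed and shielded organs and 1 between adult and seedling leaf. That fit assumes lone profiles to vary like the leaf pairs and takes their unsettled signs as deposited, so whether these probes differ is not settled either.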

How the results depend on the processing

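Alternatives on print blocks, source plates, repeated columns, first list patterns, chn1, the orientation term in organ contrasts and first-table arrays left out without that term were chosen after the data were seen, and the others were planned. Results that kept their side of the threshold with counts within 1.5 times the reported ones are not repeated here. Signal over background, the usual limit of arrays, is not used here because the tables hold no intensities. Where a count changed, the cause was not tested unless a cause is given.

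The orientation term is also the replicate block, since the second array of each pair is the swapped one. With no replicate block 375 probes passed at 2 h high (714 with it, and 96% higher against 80.3%), 3 at 4 h medium (16), 3 at 8 h low (19), 45 at 8 h high (197, and 73.3% against 53.8%) and 135 for CA against PE (71). The differences gave 240 for 8 h high minus 2 h high (579), 0 for 8 h high minus 8 h low (31, limma, 210 at unadjusted p under 0.05), 167 for 2 h high minus 4 h medium (348), 81 for 2 h high minus 8 h low (251) and 109 among the 3 regimes (291), and 1 list shift passed in adult leaf and CA against PE (0). With no replicate block 13 of the 16 named genes at 8 h high lost their calls, 8 of 20 at 2 h high, 2 of 2 at 4 h medium and at 8 h low, and 0 list shifts of the regimes did. In the organ contrasts, where the term was left out, including it gave 6 probes for exposed minus shielded (1), 42 for adult minus seedling leaf (1) and 42 among the 5 organs (0). Whether the numbers pair the arrays by plant or day is not given, and the block stands for dye orientation.

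With the other sign reading of the swapped arrays, 0 probes passed limma in adult leaf, CA against PE, each of the 4 regimes, the 4 differences that had calls and the F test among the 3 regimes. List shifts fell to 1 in the regimes (4) and 1 in the differences (3). The defence shift changed direction at 8 h high (adjusted p = 0.977), in 8 h high minus 2 h high (0.901) and in 8 h high minus 8 h low (0.884), and the carbohydrate shift at 8 h high (0.581). Correlations of regime means became 0.557 for 2 h high with 4 h medium (0.188), 0.25 for 2 h high with 8 h high (-0.078) and 0.512 for 8 h low with 8 h high (0.191). Named genes that changed sign under that reading are given with their log2 values. In CA against PE they were sps1 (0.18) and thi1-2 (0.17). At 2 h high they were zmm16 (-0.096), NIR (-0.032), OBF1 (-0.40), SE1B (-0.27), ZCAX2 (-0.27), cncr1 (-0.29), LOC542641 (0.22), chn1 (0.15), GT1 (0.069), EXPB9 (0.071), psei2 (0.095), Agp2 (0.03) and LOC541942 (0.01). At 4 h medium it was Agp2 (0.21). At 8 h low they were lhcb5 (0.58) and m28 (0.66). At 8 h high they were chn1 (-0.25), psei2 (-0.11), PAL1 (-0.18), PDIL1-1 (-0.49), lhcb5 (0.29), por (0.12), pOMT1 (0.21) and LOC100101527 (0.22). In 8 h high minus 2 h high they were chn1 (-0.40), psei2 (-0.20), LOC541942 (-0.48), Sod4A (-0.063), hir1 (-0.18), PDIL1-1 (-0.46), aba1 (-0.16), zmm16 (0.17), OBF1 (0.29), psbs1 (0.11), pOMT1 (0.24) and LOC100101527 (0.27). In 8 h high minus 8 h low they were PDIL1-2 (-0.055), MMT1 (-0.43), CNX (-0.32) and psei2 (-0.22). In 2 h high minus 4 h medium they were OBF1 (-0.21), LOC541857 (-0.068), SE1B (-0.068) and ZCAX2 (-0.17). In 2 h high minus 8 h low they were zmm16 (-0.25), glb1 (-0.12), MMT1 (-0.60), LOC100125656 (-0.59), EF1A (-0.77), xth1 (-0.40) and LOC541942 (0.21). A value under this reading is the half-difference of opposed arrays by construction, which removes what both arrays of a pair share. Beside these counts of 0, probes at unadjusted p under 0.05 numbered 139 in adult leaf, 7 for CA against PE, 8, 14, 692 and 167 at 2 h high, 4 h medium, 8 h low and 8 h high, 22 for 8 h high minus 2 h high, 69 for 8 h high minus 8 h low, 1 for 2 h high minus 4 h medium and 90 for 2 h high minus 8 h low.

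Without centring 18 probes passed in adult leaf (31), of which 15 were higher (83.3% against 96.8%), 54 at 8 h low (19), 1 for 4 h medium minus 8 h low (0), and 0 for each organ contrast (1 each). With scale normalization the counts were 15 in adult leaf, 123 for CA against PE (38 higher and 85 lower, 30.9% higher against 42.3%), 221 at 4 h medium (79 and 142, 35.7% against 50%), 9 at 8 h low (6 and 3, 66.7% against 52.6%), 17 for 4 h medium minus 8 h low, 2 for exposed minus shielded, 0 for adult minus seedling leaf and 4 among the 5 organs. Scaling moved the correlation of 4 h medium with 8 h low to 0.313 (0.424) and of 8 h low with 8 h high to 0.308 (0.191).

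Robust empirical Bayes gave 17 probes in adult leaf, 78 at 8 h low (22 and 56, 28.2% higher against 52.6%), 48 for 8 h high minus 8 h low, 1 for 4 h medium minus 8 h low, 4 for exposed minus shielded, 38 for adult minus seedling leaf and 28 among the 5 organs. Array weights gave 2694 at 2 h high (1369 and 1325, 50.8% higher against 80.3%), 778 at 4 h medium (307 and 471, 39.5% against 50%), 3 at 8 h low (3 and 0), 124 at 8 h high, 888 for 8 h high minus 2 h high, 3 for 8 h high minus 8 h low (3 and 0), 1673 for 2 h high minus 4 h medium (980 and 693, 58.6% against 97.4%), 155 for 2 h high minus 8 h low, 1167 among the 3 regimes, 10 for exposed minus shielded, 2 for adult minus seedling leaf and 28 among the 5 organs. Fits of the comparison's own arrays gave 892 for 8 h high minus 2 h high, 17 for 8 h high minus 8 h low, 1381 for 2 h high minus 4 h medium (845 and 536, 61.2% against 97.4%), 151 for 2 h high minus 8 h low and 165 among the 3 regimes. The fuller seedling leaf column moved no organ count by over 1.5 times. Probes with a value on every array gave 0 for exposed minus shielded and 0 for adult minus seedling leaf.

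With block medians set to 0 the counts were 1424 at 2 h high (840 and 584, 59.0% higher against 80.3%), 9 at 8 h low (7 and 2, 77.8% against 52.6%), 399 at 8 h high, 1323 for 8 h high minus 2 h high (570 and 753, 43.1% against 26.1%), 60 for 8 h high minus 8 h low, 0 for each organ contrast, and 5 list shifts in the differences (3). Plate medians set to 0 gave 0 in adult leaf (limma, 141 at unadjusted p under 0.05), 12 for CA against PE (11 and 1, 91.7% against 42.3%), 209 for 2 h high minus 4 h medium (180 and 29, 86.1% against 97.4%), 1 for 4 h medium minus 8 h low, 0 for adult minus seedling leaf and 1 probe at 2-fold in adult leaf (0), and cncr1 at 2 h high changed sign to -0.12. The ear taken from the profile it shares with tassel gave 0 for exposed minus shielded and 3 among the 5 organs. With the first symbol patterns 0 list shifts passed in the regimes (4) and 0 in the differences (3), where 5 lists reached 5 probes, and the defence and chaperone lists were not among them. At 1.5-fold on both arrays the counts were 5 in adult leaf (0), 106 for CA against PE (27), 277 at 2 h high (85), 7 at 4 h medium (3) and 48 at 8 h high (7), as a lower fold admits more probes.

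Named genes that lost their calls are given by setting, with their log2 value where the setting can change it. With the probes of a gene averaged they were for CA against PE thi1-2 (-0.33); at 2 h high CesA-6 (-0.36), EXPB9 (-0.22) and Agp2 (-0.23); at 4 h medium CesA-6 (-0.29) and Agp2 (-0.29); at 8 h low m28 (-0.61); at 8 h high PDIL1-2 (0.43), LOC100101527 (-0.41) and Agp2 (-0.39); for 8 h high minus 2 h high PDIL1-2 (0.41), hir1 (0.47), glb1 (-0.56), NIR (-0.56) and LOC100101527 (-0.50); for 8 h high minus 8 h low PDIL1-2 (0.62); for 2 h high minus 4 h medium NIR (0.56) and glu1 (0.36); for 2 h high minus 8 h low glb1 (0.60), EF1A (0.34), xth1 (0.63), LOC541942 (-0.66) and CesA-6 (-0.22). With block medians set to 0 they were for CA against PE sps1 (-0.70) and thi1-2 (-0.67); at 2 h high chn1 (-0.51); at 8 h low lhcb5 (-0.56) and m28 (-0.48); for 8 h high minus 8 h low MMT1 (0.94) and psei2 (0.65); for 2 h high minus 8 h low MMT1 (0.73), LOC100125656 (0.67), EF1A (0.59) and LOC541942 (-0.54). With plate medians set to 0 they were for CA against PE PDIL1-2 (1.02), sir (0.82), grp1 (-0.75), sps1 (-0.80) and thi1-2 (-0.71); at 2 h high NIR (0.29), OBF1 (0.27), SE1B (0.08), ZCAX2 (0.13), LOC542641 (-0.39), GT1 (-0.39), EXPB9 (-0.37), psei2 (-0.39) and LOC541942 (-0.31); at 8 h high PAL1 (0.34) and du1 (-0.34); for 8 h high minus 2 h high LOC541942 (0.42), hir1 (0.54), PDIL1-1 (0.51), aba1 (0.31), LOC541901 (0.50), OBF1 (-0.41) and NIR (-0.31); for 2 h high minus 4 h medium NIR (0.33), OBF1 (0.13), SE1B (0.01) and ZCAX2 (0.04); for 2 h high minus 8 h low xth1 (0.50), aba1 (-0.51), LOC541942 (-0.49) and CesA-6 (-0.59). With scale normalization they were at 8 h low lhcb5 (-0.43) and m28 (-0.28); for 2 h high minus 8 h low MMT1 (0.56), LOC100125656 (0.53), EF1A (0.40), xth1 (0.42) and LOC541942 (-0.52). With array weights they were at 8 h low lhcb5 and m28; at 8 h high LOC542721, LOC542358 and du1; for 8 h high minus 8 h low PDIL1-2, MMT1, CNX and psei2; for 2 h high minus 8 h low EF1A, xth1, aba1, LOC541942 and CesA-6. In fits of the comparison's own arrays they were for 8 h high minus 8 h low psei2; for 2 h high minus 8 h low EF1A, xth1, aba1, LOC541942 and CesA-6. Without plates 37 and 39 they were at 8 h low m28; for 2 h high minus 8 h low EF1A, xth1 and LOC541942. With probes complete on every array they were at 8 h low m28. With robust empirical Bayes they were for 2 h high minus 8 h low EF1A. Without centring they were for 2 h high minus 8 h low xth1 (0.57). With no replicate block they were at 2 h high aba1, LOC542641, ccp2, chn1, EXPB9, psei2, Agp2 and LOC541942; at 4 h medium CesA-6 and Agp2; at 8 h low lhcb5 and m28; at 8 h high CNX, psei2, PAL1, ZAG1, PDIL1-1, lhcb5, por, pOMT1, LOC100101527, Agp2, LOC542721, LOC542358 and du1; for 8 h high minus 2 h high LOC541942, ccp2, Sod4A, hir1, PDIL1-1, aba1 and LOC541901; for 8 h high minus 8 h low PDIL1-2, MMT1, CNX and psei2; for 2 h high minus 4 h medium OBF1, LOC541857, SE1B and ZCAX2; for 2 h high minus 8 h low glb1, ivr2, MMT1, LOC100125656, EF1A, xth1, aba1, LOC541942 and CesA-6.

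Leaving out each array in turn gave 15 to 510 probes in adult leaf, 4 to 313 for CA against PE, 247 to 1146 at 2 h high, 5 to 16 at 4 h medium, 3 to 1005 at 8 h low and 6 to 297 at 8 h high. The differences ran from 198 to 947 for 8 h high minus 2 h high, 0 to 660 for 8 h high minus 8 h low, 170 to 415 for 2 h high minus 4 h medium, 109 to 743 for 2 h high minus 8 h low, 0 to 129 for 4 h medium minus 8 h low and 139 to 702 among the 3 regimes. They ran from 2 to 384 for exposed minus shielded, 0 to 553 for adult minus seedling leaf and 4 to 894 among the 5 organs, with the highest counts without adult leaf array 1. List shifts ran from 1 to 4 in the regimes, 2 to 4 in the differences and 0 to 1 in adult leaf and CA against PE. In these fits a lone array is assumed to vary like the other groups. In adult leaf and CA against PE leaving out an array with the orientation term kept leaves no residual degree of freedom, so it was run without that term.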

Other observations

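Both tests below were chosen only after the result was seen, and all single profiles are as deposited, so that turning a profile exchanges higher and lower.

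Gene groups of single profiles that lay beyond percentile 5 or 95 of random lists from all probes, with no replicate and no p, were as follows besides those of the PE-covered leaf, and some lists lie there by chance. In tassel, 17 of 19 chromatin probes were negative (median -0.21, percentile 0.56), as were 4 of 5 cytoskeleton probes (median -0.41, percentile 0.33) and 7 of 9 chaperone probes (median -0.24, percentile 2.12), with lignin and cell wall genes at percentile 3.1 and translation factors at 4.33 (6.1 and 7.53 among random lists of named probes). In ear, chaperones had a median of -0.49 (percentile 0.69), photosynthesis genes of -0.39 (percentile 3.23) and chromatin genes of -0.26 (percentile 4.5, and 7.55 among named probes). In root, the floral markers had a median of 0.50 (percentile 99.51), with zmm16 at 0.84 and m28 at 0.82, and lignin and cell wall genes lay at percentile 4.54 (5.87 among named probes). In seedling leaf, ribosomal proteins (median 0.37, percentile 97.96) and nitrogen genes (median 0.33, percentile 97.99) lay high and cytoskeleton genes (median -0.53, percentile 0.24) and lignin and cell wall genes (median -0.29, percentile 1.49) low. On adult leaf array 2 alone, 6 of 6 photosynthesis probes were positive (median 0.51, percentile 97.44), while on array 1 8 of 14 were negative (median -0.08, percentile 8.92). Array 2 also had chaperones at percentile 95.96 and aquaporins at 3.66 (11.36 among named probes), and array 1 cytoskeleton genes at 1.71.

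Profiles correlated across probes, which are not independent replicates, at 0.493 between root and ear and 0.388 between tassel and ear. The PE-covered leaf correlated at 0.317 with CA against PE array 1 and 0.151 with array 2 and, over named genes, at 0.274 with 8 h high, where the Spearman value was 0.083. Over named genes adult leaf array 2 correlated at 0.402 with 2 h high and at -0.359 with 8 h high, and array 1 at -0.081 and 0.132.

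Of 6 probes of protein folding genes of the endoplasmic reticulum at 8 h high, those of PDIL1-1, CNX and 1 of 2 of PDIL1-2 passed, and PDIL5-4 (-0.25), crt2 (-0.09) and the second PDIL1-2 probe (0.16) did not. The group was picked because 3 of its genes had risen there, so its rise at 8 h high is no test of it. The hypothesis that direct UV-B may raise genes of this group in adult leaf was tested in CA against PE. The probes tested there were 2 of PDIL1-2 (0.90 and 0.08) and 1 of crt2 (0.16), and none of PDIL1-1 or CNX. These 3 probes had a median of 0.16, at percentile 94.98 of random lists of named probes. That percentile lies just under the bound set for it and with 3 probes the test does not decide.

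Photosynthesis genes lay low in the PE-covered leaf, with psbs1 at -0.82, rca1 at -0.84, ssu1 at -0.96 and lhcb5 at -1.11. The hypothesis that the same list could be low at 8 h high as a whole was tested by its median there, -0.04 over 16 probes, at percentile 13.84 of random lists of named probes, which does not decide. In camera, which weighs the large members more, the list had passed downward at 8 h high (adjusted p = 0.0102, 0.00448 with an estimated correlation, 13 of 16 probes negative), a call lost without 8 h high array 1 (0.133) or array 2 (0.0541). There lhcb5 and psbs1 were the 2 members that passed limma.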
